A study of Mus musculus with 10 samples.

How the data were processed

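RNA sequencing measured gene expression in 10 libraries of immortalised mouse embryonic fibroblasts (MEFs, connective-tissue cells grown from embryos). The cells were labelled as carrying intact Slfn2 (WT-labelled) or a knockout of it (KO-labelled), and were left untreated or given 5000 IU/ml of mouse interferon-β (IFN-β) for 6 h. There were 3 libraries in each WT-labelled group and 2 in each KO-labelled group. Per the labels, the replicates are wells plated from a WT culture and a KO culture. Each p-value below thus measures the spread between replicate libraries and not between independently derived lines. Unless the block is used, that spread includes whatever libraries of the same replicate number share.

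Total RNA was made into directional libraries with a stranded kit, per the series' design text. Per the submitters' processing notes, reads were trimmed with cutadapt 1.13, aligned with STAR 2.5.2a to the mm10 genome, and processed with HTSeq and DESeq2. The annotation, the strand setting and any filter are not stated. The deposited values are a signal scaled by library: gene read counts that the authors divided by a size factor, with 23337 gene symbols in each library. Every value was a whole multiple of what 1 read is worth in its library, within a tolerance of 0.001 reads (100% of values in each library), so the whole reads were recovered. The recovered totals ran from 13565815 to 16329729 reads per library, which sets the depth behind each value. A floor of 3 reads per library equals 2.73 to 3.29 normalised reads. Intervals on ratios and floors cover counting error only.

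Because the deposited unit is not a raw count, the quasi-likelihood count test planned for raw counts was replaced as the reported test. The reported test is limma-trend (limma 3.58.1, R 4.3.3) on log2 of the normalised read count plus a pseudocount of 1, with a mean for each of the 4 groups over all 10 libraries, so that the groups share an estimate of the spread. Genes passed a low-count filter (filterByExpr of edgeR 4.0.16, minimum count 10, on the recovered reads), which left 12313 genes. A gene is said to change at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Every adjusted p for a gene in the text is from limma with this adjustment unless another tool is named. Fold changes are on the log2 scale with the pseudocount, which understates the change of low genes. Where a group held 0 reads, the text gives a lower bound against the floor of 3 reads per library, and where it held 1 to 3 reads, the ratio of means with its 95% counting interval. The 5 comparisons were IFN-β against untreated in each labelled genotype, KO-labelled against WT-labelled in each treatment, and the interaction, which tests whether the IFN-β response differs between genotypes.

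The replicate numbers pair the samples. Deviations from group means correlated at 0.48 to 0.87 between libraries of the same number in different groups, each above the limit of 0.1, while the highest value between different numbers was 0.32. All 6 WT-labelled libraries correlated best with the WT-labelled library of their own number. Nothing in the labels says what a number marks, so the pairing rests on the data. Without the block, leaving out 1 library changes the balance of the numbers between groups. A result that moves then can reflect the number as well as the library. The reported test has no block, as fixed before the data were examined, and the value with the replicate number as a block stands beside a result where the block changes the call or moves a count by more than 1.5 times.

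Gene lists fixed before the data were examined were tested with camera (limma, preset correlation 0.01), adjusted over the lists of a comparison with at least 5 tested members. A list's adjusted p in the text is from camera. The lists were the Schlafen family, interferon-stimulated genes, interferon-inducible GTPases, MHC class I and antigen processing, interferon receptor with JAK-STAT and IRF components, NF-κB target genes, NF-κB pathway components, interferon-responsive chemokines and cytokines, cell cycle, p53 targets, fibroblast and extracellular matrix, contractile and serum-response genes, Hox and positional identity, stress and unfolded protein response, immediate early genes, cholesterol biosynthesis, imprinted genes, sex-linked transcripts, mitochondrial transcripts, and markers of macrophages, epithelium, endothelium, muscle and skeleton, and neural cells. The 13 mitochondrial protein-coding transcripts are not among the gene symbols in the data, so that list has no result.

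The named genes follow a rule fixed before the data were examined. They are the Schlafen family, Ifit1, Isg15, Cxcl10 and Nfkbia in every comparison, then the 8 genes with the largest rise and the 8 with the largest fall per comparison among genes that passed the test with an average log2 CPM of at least 1 and groups that do not overlap (predicted and clone names left out), and up to 4 passing members of each list. Any other gene is named as chosen after its values were seen.

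Alternatives were edgeR's quasi-likelihood test on the recovered reads with TMM, with DESeq2-type size factors and with library totals only, DESeq2 1.42.0, no low-count filter, a minimum count of 50, a fold threshold, the replicate block, only the groups compared, and leaving out each library in turn. Added after the data were seen were pseudocounts of 0.5 and 4, edgeR with TMM and the block, and leaving out all libraries numbered 1. The block over numbers 1 and 2 only was added then too. So was leaving neighbouring genes of chromosomes 5 and 9 out of the NF-κB target list and of chromosome 19 out of the interferon-stimulated list. The edgeR test with TMM and no block was the test planned for raw counts, kept as an alternative once the unit was seen. The test was run on simulated reads with 100 genes changed by a log2 fold change of 1 and 100 by 2, over 12313 genes. For IFN-β in WT-labelled cells, 20% of the smaller and 64% of the larger changes were recovered (80% and 94% with the block). The shares were 5% and 56% for IFN-β in KO-labelled cells (60% and 89%), 7% and 54% for KO-labelled against WT-labelled untreated (68% and 97%), 2% and 57% with IFN-β (61% and 94%), and 0% and 19% for the interaction (37% and 88%). In the same order, 0 of the genes that passed without the block were unchanged ones, against 14 of 188, 10 of 159, 15 of 180, 20 of 175 and 8 of 133 with it. Each of these shares is above 0.05. The threshold bounds the average share and each comparison was simulated in 1 draw, so a single share does not show that the block exceeds it. In the data 767 and 807 genes passed between the genotypes untreated and with IFN-β, more than the simulation changed. The adjustment is less strict with more changed genes, so the shares need not carry over to those comparisons. Gene positions came from GENCODE M21 on GRCm38, with RefSeq synonyms, and placed 12191 of the 12313 tested genes.

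Slfn2 is the targeted gene, and gene-level reads cannot show a deletion of part of it. Its level in the libraries labelled KO was higher untreated and lower with IFN-β than in those labelled WT. These reads do not decide the label, so the 2 are called KO-labelled and WT-labelled throughout. Genes of the Schlafen, Ifit, guanylate-binding protein and MHC class I families have close copies, and reads shared between copies may be split or lost in counting, so single members of these families carry that uncertainty.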

Results

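Gene expression was measured by stranded RNA sequencing in 10 libraries of immortalised mouse embryonic fibroblasts. There were 3 WT-labelled libraries untreated, 3 WT-labelled with IFN-β, 2 KO-labelled untreated and 2 KO-labelled with IFN-β, where IFN-β, a type I interferon, was given at 5000 IU/ml for 6 h. The WT-labelled libraries held 13814658, 14758646 and 13565815 reads untreated and 15265097, 14762714 and 15173970 with IFN-β. The KO-labelled libraries held 14600785 and 14992026 untreated and 14990710 and 16329729 with IFN-β. Between 13658 and 14311 genes had a read in each library. Genotype lay along the leading principal component (42.1% of the variance), IFN-β along the next (25.4%) and the replicate number along the one after (20.4%). Between the libraries numbered 1 and those numbered 2, 5983 genes passed the test after the groups were accounted for. The question behind the series is how Slfn2 acts on type I interferon responses and on the NF-κB pathway.

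Slfn2, a Schlafen family gene that interferon is known to induce and the target of the knockout, lies on chromosome 11 at 83065112 to 83070678 (GRCm38, plus strand, protein-coding). Its normalised read counts were 18.7, 17.4 and 15.5 in untreated WT-labelled cells and 527, 449 and 573 with IFN-β. In KO-labelled cells they were 46.1 and 34.9 untreated, and 75 and 171 with IFN-β. Untreated, the KO-labelled mean was thus above the WT-labelled mean (log2 fold change 1.18 ± 0.36 SE, adjusted p = 0.091, and 0.039 with the replicate block). With IFN-β, the KO-labelled mean was lower (−2.17 ± 0.36, adjusted p = 0.0082), a call lost without KO-labelled IFN-β library 1 (adjusted p = 0.055). Reads over the whole gene cannot show whether part of it is deleted, and the deleted part is not stated. Neither the untreated level nor the lower level with IFN-β thus decides whether the label holds.

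**Figure D1:**
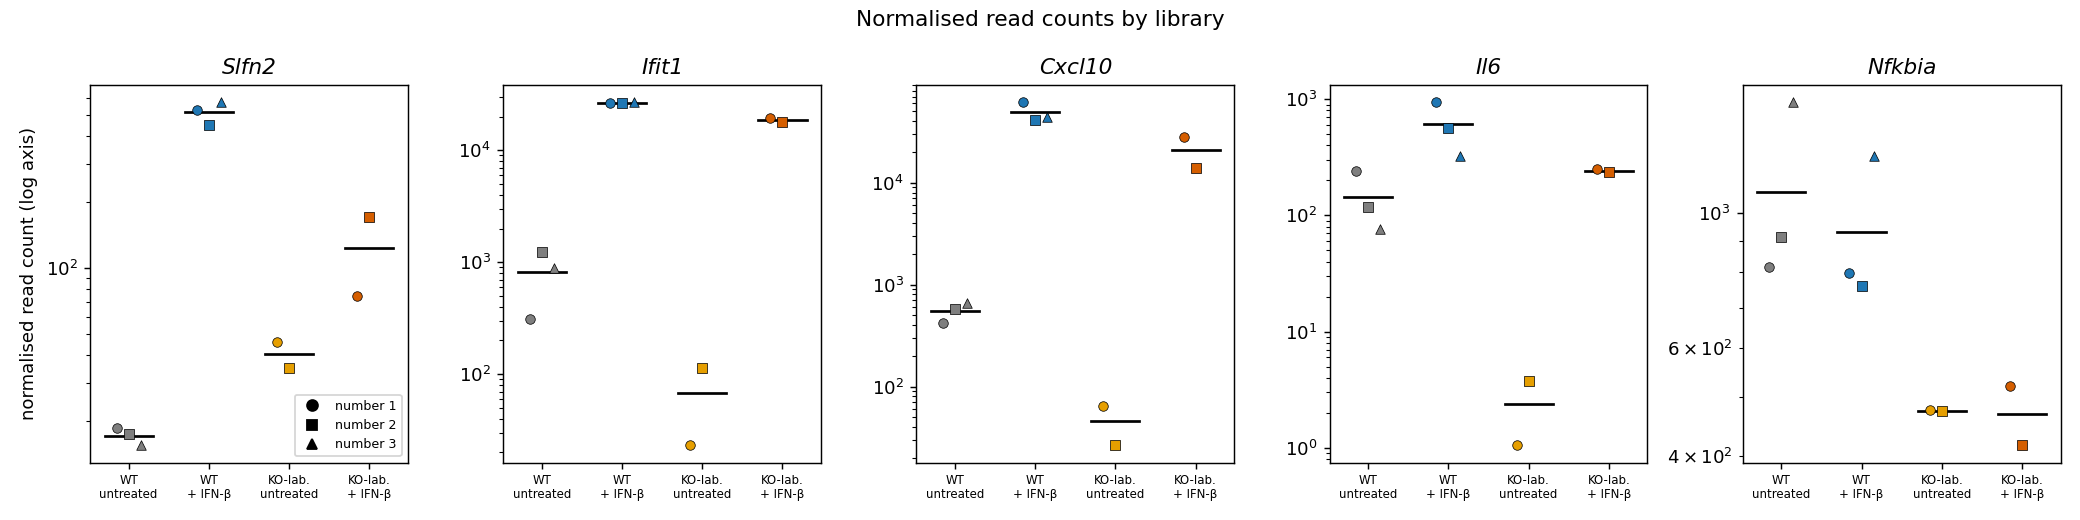
Normalised read counts (log axis) of Slfn2, Ifit1, Cxcl10, Il6 and Nfkbia in each of the 10 libraries by group, with markers for the replicate number and a bar at each group mean. Slfn2 lies between 15.5 and 46.1 in the untreated libraries, at 75 and 171 in the KO-labelled libraries with IFN-β and at 449 to 573 in the WT-labelled ones.

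The response of WT-labelled cells to IFN-β shows which genes interferon signalling moves in these fibroblasts. Usp18, a protease that removes ISG15 and restrains the interferon receptor, went from 7.97 ± 11.2 to 5060 ± 988 normalised reads (SD, n = 3 each), a log2 fold change of 9.94 ± 0.74. Mx1 and Mx2, of the dynamin-like GTPase family, rose by 9.91 ± 0.53 and 8.86 ± 0.68 on the log2 scale. The GTPase Iigp1 rose by 9.33 ± 0.36, the antiviral enzyme Rsad2 by 8.15 ± 0.42, and Mpeg1, a pore-forming protein, by 8.05 ± 0.63. Adjusted p for all of these ran from 3.2e-06 to 9.6e-05. Mx2 and the chemokine gene Cxcl11 are annotated in GENCODE M21 as polymorphic pseudogenes, so their reads need not stand for a working protein. Pydc3 held 2 reads over the untreated libraries, and the ratio of means was 743 (95% counting interval 205 to 6140). Oas2, a sensor of double-stranded RNA, held 3 untreated reads, with a ratio of 498 (170 to 2420). Altogether 272 genes passed the test and all were higher, while the replicate block gave 609, of which 576 were higher and 33 lower. With the block the total was 368 without WT-labelled untreated library 3, 400 without WT-labelled IFN-β library 1 and 363 without WT-labelled IFN-β library 3, and the 33 lower genes became 2 to 23 over the libraries left out.

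Of 60 tested interferon-stimulated genes, 55 rose (58 adjusted over the list alone), with a median log2 fold change of 4.8. Ifit1 went from 809 ± 468 to 26600 ± 292 (log2 fold change 5.25 ± 0.60, adjusted p = 0.00098) and Isg15 from 178 ± 45.1 to 5950 ± 488 (5.09 ± 0.43, adjusted p = 0.00014). Ifitm3 (1.25, adjusted p = 0.119) and Mov10 (1.85, adjusted p = 0.2) were among those that did not pass. All 17 interferon-inducible GTPases rose (17 adjusted over the list alone), Igtp by 7.68 ± 0.37 and Tgtp1 by 7.62 ± 0.61. Of 19 MHC class I and antigen processing genes, 12 rose (18 adjusted over the list alone), among them the peptide transporter Tap1 (7.90 ± 0.71) and Nlrc5, the regulator of MHC class I genes (5.20 ± 0.51). Of 11 chemokines and cytokines that respond to interferon, 8 rose (9 adjusted over the list alone). Cxcl10, which draws T cells, went from 552 ± 124 to 49100 ± 11000 (6.47 ± 0.37, adjusted p = 1.6e-05), and Il15 from 0 reads to 69.4 ± 32.0, at least 22.4-fold higher. The adjusted p of these 4 lists was 1.3e-150, 4.1e-55, 7.4e-37 and 1.1e-27, and each list passed with an estimated correlation as well (adjusted p = 0.002, 0.0045, 0.017 and 0.00068).

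All 8 tested Schlafen genes rose in WT-labelled cells (8 adjusted over the list alone; list adjusted p = 1.1e-25, and adjusted p = 0.0045 with an estimated correlation). Slfn2 rose by 4.83 ± 0.32 on the log2 scale, 28.4-fold (adjusted p = 3.7e-05). Slfn9, Slfn5 and Slfn10-ps rose by 6.46 ± 0.74, 5.90 ± 0.83 and 3.98 ± 0.44. Slfn8 held 3 untreated reads, with a ratio of 165 (95% counting interval 56.3 to 805), and Slfn4 held 0, so it was at least 29.8-fold higher. Slfn1, also from 0 reads, was at least 4.86-fold higher (adjusted p = 0.015), and Slfn3, from 3 reads, had a ratio of 12.3 (3.89 to 62.1; adjusted p = 0.021). The Slfn3 call was lost without any 1 of the 6 WT-labelled libraries (adjusted p up to 0.14) and the Slfn1 call without any of them but IFN-β library 2 (up to 0.088). The list median was 5.4, or 4.9 with the 2 genes from 0 reads at their bounds.

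Among 25 interferon receptor, JAK-STAT and IRF genes, 3 rose in WT-labelled cells (6 adjusted over the list alone, 7 with the block): Irf5 (3.23 ± 0.34), Irf2 (1.59 ± 0.24), both transcription factors, and Socs1, a feedback inhibitor of JAK kinases (2.15 ± 0.19). Of 33 NF-κB pathway components, 2 rose (2 adjusted over the list alone), the double-stranded RNA receptor Tlr3 (5.43 ± 0.39) and the adaptor Myd88 (1.82 ± 0.14). These 2 lists passed at adjusted p = 0.003 and 0.012, but not with an estimated correlation (adjusted p = 0.085 and 0.057). Of 49 NF-κB target genes, 1 rose, the complement gene Cfb (3.46 ± 0.56, adjusted p = 0.0099), or 4 adjusted over the list alone and 10 with the block. The Cfb call was lost without WT-labelled IFN-β library 2 or 3 (adjusted p up to 0.073). The list had adjusted p = 0.068 (adjusted p = 0.35 with an estimated correlation), 0.039 with the block (0.12 with the block and an estimated correlation), 0.016 without WT-labelled untreated library 3 and 0.012 without WT-labelled IFN-β library 2. Nfkbia, the NF-κB inhibitor that NF-κB itself induces, had a log2 fold change of −0.20 ± 0.27 (adjusted p = 1).

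Few genes of the remaining lists passed with IFN-β in WT-labelled cells. The stress-response transcription factor Atf3 rose (1.58 ± 0.27), the only one of 17 stress genes (1 adjusted over the list alone, 5 with the block), and it and the RNA-binding Zfp36 (0.94 ± 0.19) were the 2 of 15 immediate early genes that did (3 adjusted over the list alone, 3 with the block). The p53 list had 1 of 22 (1 adjusted over the list alone, 3 with the block), Eda2r (1.72 ± 0.30), lost without WT-labelled IFN-β library 1 or 3 (adjusted p up to 0.09). The Atf3 call was lost without any WT-labelled library but untreated library 1 (up to 0.071), and the Zfp36 call without any library but the KO-labelled IFN-β ones (up to 0.2). The stress list had adjusted p = 0.00049 (adjusted p = 0.36 with an estimated correlation, and 0.075 without WT-labelled IFN-β library 1). The immediate early list had adjusted p = 0.043 (adjusted p = 0.65 with an estimated correlation, 0.057 with the block, and 0.37, 0.18 and 0.89 without WT-labelled untreated library 2, untreated library 3 and IFN-β library 1). None of 31 cell cycle genes passed in limma, but the list was lower by a median of −0.13 (adjusted p = 0.015, adjusted p = 0.65 with an estimated correlation, and 0.14, 0.081 and 0.062 without WT-labelled untreated library 3, IFN-β library 1 and IFN-β library 2).

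In KO-labelled cells the same treatment asks how the response looks with Slfn2 targeted. Mx1 rose by 10.30 ± 0.65 on the log2 scale, from 2.46 ± 0.516 to 4670 ± 2550 normalised reads (SD, n = 2 each), Iigp1 by 10.20 ± 0.44, Ifit3 by 9.94 ± 0.39, and Irf7, the transcription factor that amplifies interferon production, by 8.92 ± 0.70, with adjusted p from 3.7e-06 to 0.00014. Usp18 held 2 untreated reads and had a ratio of means of 6690 (95% counting interval 1850 to 55200), Rsad2 held 2 and had 1310 (362 to 10800), and Mx2 held 1 and had 4730 (848 to 187000). Cxcl10 rose from 45.7 ± 27.3 to 21100 ± 10100 (8.87 ± 0.45, adjusted p = 2.1e-05). Altogether 225 genes rose and 2 fell, and the replicate block gave 415 and 14, 429 in all. That total was 267 without KO-labelled IFN-β library 2, and the 14 became 0 to 47 over the libraries left out. The 2 that fell were Mtss1, an actin-binding protein (−1.09 ± 0.22, adjusted p = 0.045), and the clone-named 1110021J02Rik, chosen after its values were seen. The count of 227 was 132 without KO-labelled IFN-β library 2. The Mtss1 call was lost without any 1 of 9 libraries, all but WT-labelled untreated library 3 (adjusted p up to 0.37).

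Of the 60 interferon-stimulated genes, 55 rose in KO-labelled cells (57 adjusted over the list alone), with a median of 5.2 (5.1 with the 4 genes from 0 reads at their bounds). Ifit1 rose by 8.46 ± 0.73 (adjusted p = 0.00025) and Isg15 by 6.39 ± 0.52 (adjusted p = 0.00018). Of 17 GTPases 15 rose (17 adjusted over the list alone), among them Tgtp2 (8.05 ± 0.42) and Gbp3 (8.04 ± 0.86). Of 19 MHC class I genes 10 rose (18 adjusted over the list alone, 17 with the block), including Tap1 (7.56 ± 0.87). Of the 11 chemokines and cytokines 7 rose (9 adjusted over the list alone), including Cxcl11 (7.62 ± 0.70) and Il15, at least 19.5-fold higher from 0 reads. These lists had adjusted p of 1.1e-195, 2.7e-65, 5.4e-46 and 8e-31, and adjusted p = 0.00092, 0.0038, 0.0097 and 0.00049 with an estimated correlation. Of 25 receptor, JAK-STAT and IRF genes 3 rose (4 adjusted over the list alone, 5 with the block), Irf5 (3.22 ± 0.41), Socs1 (3.15 ± 0.23) and Irf2 (1.91 ± 0.29), and of 33 NF-κB components 2 rose (2 adjusted over the list alone), Tlr3 (5.01 ± 0.48) and Myd88 (2.00 ± 0.17). The Irf2 call was lost without KO-labelled untreated library 1 or KO-labelled IFN-β library 2 (adjusted p up to 0.095). The JAK-STAT list had adjusted p = 0.0075, and adjusted p = 0.14 with an estimated correlation, and it did not pass without either of those same 2 libraries (0.26 and 0.21). The NF-κB component list had adjusted p = 0.1.

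Among the 49 NF-κB target genes, 3 rose with IFN-β in KO-labelled cells (4 adjusted over the list alone, 6 with the block), all cytokines that draw or activate immune cells. Il6 went from 2.41 ± 1.92 to 243 ± 11.5 (6.29 ± 0.64, adjusted p = 0.00062), and the chemokines Ccl7 and Ccl2 rose by 2.74 ± 0.56 (adjusted p = 0.046) and 2.48 ± 0.46 (0.025). In WT-labelled cells Il6 had a log2 fold change of 2.09 ± 0.53 (adjusted p = 0.115, and 0.0132 with the block) and Ccl2 1.22 ± 0.37 (0.26, and 0.00191 with the block). The Ccl2 and Ccl7 calls were lost without any 1 KO-labelled library, except that Ccl7 passed without KO-labelled untreated library 2. They were also lost without library 2 of either WT-labelled group, and Ccl7 without WT-labelled IFN-β library 1 or 3 (adjusted p up to 0.22 for Ccl2 and 0.42 for Ccl7). The list passed at adjusted p = 0.0075, but not with an estimated correlation (adjusted p = 0.15), without KO-labelled untreated library 2 (0.24) or without KO-labelled IFN-β library 1 (0.086). Nfkbia had a log2 fold change of −0.03 ± 0.33 (adjusted p = 1).

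Of the 8 Schlafen genes, 3 rose in KO-labelled cells (6 adjusted over the list alone, 5 with the block): Slfn9 (7.04 ± 0.91), Slfn8 (5.62 ± 0.63) and Slfn10-ps, which held 1 untreated read and had a ratio of 108 (19.1 to 4320). Slfn5 (4.41 ± 1.02, adjusted p = 0.089) and Slfn4 (from 0 reads, adjusted p = 0.11) passed with the block (0.013 and 0.033). Slfn2 had a log2 fold change of 1.48 ± 0.39 (adjusted p = 0.18, and 0.084 with the block), and Slfn1 and Slfn3 stayed at or under the floor in both groups. The list had adjusted p = 7.3e-18, and adjusted p = 0.0096 with an estimated correlation. With the block and an estimated correlation it did not pass (0.066).

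The interaction asks whether the response differs between the genotypes. No gene passed in limma (36 at an unadjusted p under 0.05, and 151 with the replicate block) or in edgeR (39, and 140 with the block). DESeq2 called Slfn2 (41 at an unadjusted p under 0.05). Each of these counts is below 0.05 of the tested genes, the share expected if no response differed. In these data the tests were thus conservative, and 0 calls do not show that the responses were equal. The simulation with the block did not behave so, as 8 of 133 passing genes were unchanged ones. For Slfn2 DESeq2 gave −3.31 ± 0.57 on the log2 scale, a smaller rise in KO-labelled cells (DESeq2 adjusted p = 0.00014). For the same gene limma gave −3.35 ± 0.50 (unadjusted p = 9e-05, adjusted p = 1, and 0.4 with the block). With the block and a library left out, Cxcl10 passed without WT-labelled untreated library 1, Plscr2 without KO-labelled untreated library 1, Gbp3, Ifih1, Il6 and Oasl2 without KO-labelled untreated library 2, and Slfn2 without KO-labelled IFN-β library 2, all but Slfn2 and Cxcl10 chosen after their values were seen. These counts of 1, 1, 4 and 1 stand against 0 with all libraries. Cxcl10 had 2.39 ± 0.59, Ifit1 3.21 ± 0.94, Isg15 1.31 ± 0.68 and Nfkbia 0.17 ± 0.43, each with adjusted p = 1. Slfn9 had 0.58 ± 1.18, Slfn10-ps a fitted value of 1.24, and Slfn1, Slfn3, Slfn4, Slfn5 and Slfn8 fitted values from −3.10 to −0.87. Across the 295 genes that passed in either genotype, every log2 fold change had the same sign in both, and 204 genes rose in both, where 4.97 would if the calls were independent. Over these genes Pearson's r was 0.91 and Spearman's rho 0.91, and over all tested genes 0.90 and 0.63, although genes are not independent replicates. The rho of 0.63 fell to 0.29 without KO-labelled untreated library 2 and 0.35 without KO-labelled IFN-β library 1. Either removal leaves the replicate numbers unequal between the 2 KO-labelled groups. How far the fall reflects this was not tested. With the block, 386 genes rose in both. Without the block, the 204 became 128 when KO-labelled IFN-β library 2 was left out.

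**Figure D2:**
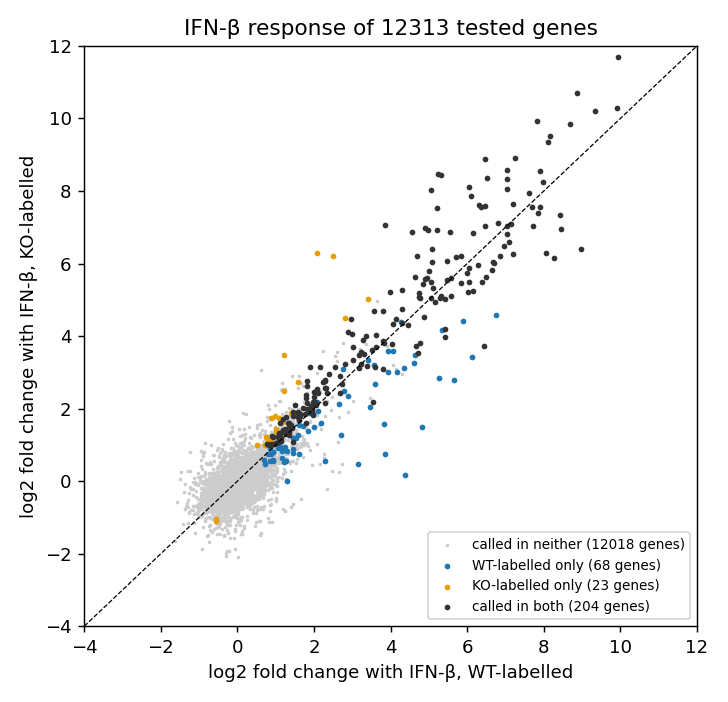
Log2 fold change with IFN-β in KO-labelled cells (vertical) against WT-labelled cells (horizontal) for 12313 tested genes, coloured by the genotype in which the gene passed the test, with a dashed line of equal change. The 204 genes that rose in both lie along the line, with r = 0.91 over the 295 genes that passed in either.

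As sets, 4 lists passed the interaction test at the preset correlation of 0.01. The correlations estimated for them, in the order below, were 0.28, 0.44, 0.5 and 0.29. The 60 interferon-stimulated genes responded more in KO-labelled cells by a median of 0.36 (adjusted p = 1.5e-22). The 17 GTPases did so by 0.68 (0.00015) and 19 MHC class I genes by 0.22 (7e-04). The 8 Schlafen genes responded less, by a median of −1.5 (3.2e-11). That list includes the target Slfn2 (−3.35 ± 0.50) and was not tested without it. Slfn1, Slfn3 and Slfn4, near Slfn2 on chromosome 11, held 0 reads in untreated KO-labelled cells, so their values depend on the pseudocount. Slfn9 (0.58 ± 1.18) and Slfn10-ps (1.24) went the other way. None of the 4 lists passed with an estimated correlation (adjusted p = 0.22, 0.61, 0.76 and 0.12). Adjusted over the list alone, 0, 0, 0 and 1 of their genes passed in limma, and 5, 4, 1 and 1 with the block. The interferon-stimulated list did not pass without KO-labelled untreated library 1 (median −0.089, adjusted p = 0.79). The Schlafen list did not pass without KO-labelled untreated library 2 (0.057). The GTPases did not pass without WT-labelled untreated library 3 (0.082), WT-labelled IFN-β library 1 (0.17), KO-labelled untreated library 1 (0.67) or KO-labelled IFN-β library 2 (0.99), nor the MHC class I list without WT-labelled untreated library 2 (0.25), KO-labelled untreated library 1 (0.24) or KO-labelled IFN-β library 2 (0.87). NF-κB targets had a median of 0.062 (adjusted p = 0.14, and 0.047 with the block; 0.61 and 0.29 with an estimated correlation), passing without WT-labelled untreated library 2 (0.011) or IFN-β library 3 (0.029), and NF-κB components, the JAK-STAT list and the chemokines had adjusted p of 0.49, 0.86 and 0.66.

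The KO-labelled and WT-labelled lines differed widely before treatment. With 1 line of each genotype, this comparison cannot tell an effect of the knockout from other differences between the lines. The same holds for the comparison with IFN-β and for the interaction. Genes higher in KO-labelled cells were led by Mef2c, a transcription factor of muscle and other lineages, which went from 1.33 ± 1.16 in WT-labelled (n = 3) to 392 ± 179 normalised reads (SD, n = 2), a log2 fold change of 7.48 ± 0.67. Perp, a p53 target at cell junctions (7.37 ± 0.58), the haematopoietic transcription factor Lyl1 (6.74 ± 0.56), the secreted peroxidase Gpx3 (6.01 ± 0.45), Kctd12 (5.85 ± 0.90) and the somite transcription factor Meox1 (5.70 ± 0.79) followed. Sox2, a stem and neural cell factor, held 0 reads in WT-labelled cells and was at least 57.8-fold higher, and Klhl13 held 2 reads there, with a ratio of 386 (95% counting interval 106 to 3190). Lower in KO-labelled cells were the acute-phase gene Saa3, at 2580 ± 1490 in WT-labelled and 2 reads in KO-labelled cells (ratio 2610, 721 to 21500), the neutrophil chemokine Cxcl5 (−9.24 ± 0.53), the iron-binding protein Lcn2 (−7.78 ± 0.85), the protocadherin Pcdh7 (1 read, ratio 709, 127 to 28000), and Mmp3 and Hp, both at 0 reads and at least 91.6-fold and 94.1-fold lower. In all, 369 genes were higher and 398 lower, and the block gave 1663 and 1612. The block total of 3275 fell to 1970 without KO-labelled untreated library 1 and 1243 without KO-labelled untreated library 2. The total of 767 fell to 423 without WT-labelled untreated library 3, 441 without KO-labelled untreated library 1 and 340 without KO-labelled untreated library 2.

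NF-κB target genes stood lower as a group in untreated KO-labelled cells. Of the 49 tested, 17 were lower (25 adjusted over the list alone, 33 with the block), with a median log2 fold change of −1.5 (list adjusted p = 4.4e-16, and adjusted p = 0.0092 with an estimated correlation). The 4 with the largest fitted change were Saa3, Cxcl5, Mmp3 and Lcn2. Mmp3 held 0 reads in KO-labelled cells, so its place among them depends on the pseudocount. Chosen after their values were seen, the complement gene C3 (−6.89 ± 0.58, adjusted p = 0.000263), Il6 (−5.39 ± 0.59, 0.0011) and Ccl2 (−4.17 ± 0.42, 0.000681) were also lower. Nfkbia was 1080 ± 384 in WT-labelled and 474 ± 1.39 in KO-labelled cells (−1.14 ± 0.30, adjusted p = 0.059, and 0.0023 with the block). The list's median lay between −1.9 and −0.93 and passed whichever library was left out. Of 33 NF-κB pathway components 1 was higher (1 adjusted over the list alone; 3 higher and 3 lower with the block), the deubiquitinase Cyld, which restrains NF-κB (1.22 ± 0.17, adjusted p = 0.0039), and the list had adjusted p = 1.

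**Figure D3:**
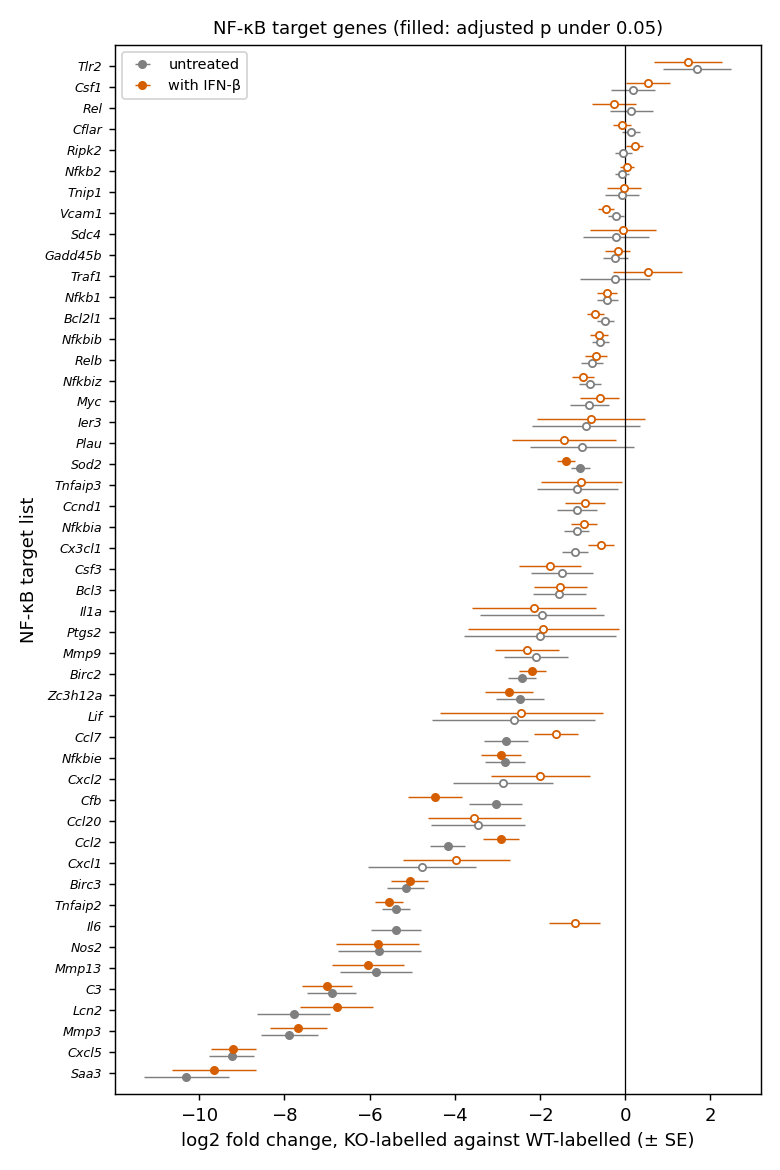
Log2 fold change of KO-labelled against WT-labelled cells (± SE) for the 49 tested NF-κB target genes, untreated (grey) and with IFN-β (orange), filled where the adjusted p is under 0.05. The medians lie at −1.5 and −1.4, and 17 and 15 genes are lower at that threshold. Cxcl1, Mmp3 and Mmp13 held 0 reads in untreated KO-labelled cells, and Mmp3 with IFN-β too, so their plotted values depend on the pseudocount.

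Several interferon-stimulated genes were lower in KO-labelled cells before treatment. Cxcl10 was 552 ± 124 in WT-labelled and 45.7 ± 27.3 in KO-labelled cells (−3.68 ± 0.41, adjusted p = 0.0013), Rsad2 held 2 reads in KO-labelled cells (ratio 31.1, 95% counting interval 8.37 to 261), and Oasl1 also held 2 (34.6, 9.33 to 290). Ifit1 was 809 ± 468 and 68.5 ± 64.3 (−3.73 ± 0.67, adjusted p = 0.012), a call lost without KO-labelled untreated library 1 (0.056), and Isg15 had −0.92 ± 0.48 (adjusted p = 0.32). Of the 60 interferon-stimulated genes, 8 were lower and 1, Bst2 (1.27 ± 0.29), higher (11 in all adjusted over the list alone; 14 and 4 with the block). The list had a median of −0.31 (adjusted p = 0.0061, and adjusted p = 0.74 with an estimated correlation), which became 0.17 without KO-labelled untreated library 1 (adjusted p = 0.7), −0.21 without WT-labelled untreated library 2 (0.059) and 0.11 without all libraries numbered 1 (0.87). Without the neighbouring chromosome 19 genes Ifit1, Ifit2, Ifit3, Gm14446 and I830012O16Rik, a choice made after their values were seen, it was −0.20 and did not pass (0.1). Of 17 GTPases 3 were lower (9 adjusted over the list alone, 9 with the block), Iigp1 (−1.64 ± 0.40), Tgtp2 (−1.84 ± 0.38) and Irgm1 (−0.81 ± 0.17). All 3 calls were lost without WT-labelled untreated library 3, WT-labelled IFN-β library 2 or KO-labelled untreated library 1, Irgm1 also without WT-labelled IFN-β library 3, and Iigp1 also without that library, WT-labelled untreated library 1, WT-labelled IFN-β library 1 or KO-labelled untreated library 2 (adjusted p up to 0.22 for Iigp1, 0.11 for Tgtp2 and 0.13 for Irgm1). The 17 had a median of −1.6 (adjusted p = 0.00017, and adjusted p = 0.7 with an estimated correlation).

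Few genes of the other interferon-related lists passed before treatment. Among the chemokines and cytokines, Il7, a lymphocyte growth factor, was higher (3.34 ± 0.43, adjusted p = 0.0023) and 2 of 11 were lower, Cxcl10 and Ccl5 (−2.31 ± 0.46, adjusted p = 0.0201, lost without WT-labelled untreated library 2 or KO-labelled untreated library 1, up to 0.11), with 3 in all adjusted over the list alone and list adjusted p = 0.57. Of 19 MHC class I genes 1 was lower (1 adjusted over the list alone), Nlrc5, with 1 read in KO-labelled cells (ratio 45.7, 7.92 to 1830). With the block 1 was higher and 2 lower (3 adjusted over the list alone). The MHC class I list had adjusted p = 0.57 and a median of −0.19, or −0.59 without KO-labelled untreated library 2. The JAK-STAT list had 1 of 25 lower (2 adjusted over the list alone; 3 higher and 7 lower with the block; list adjusted p = 0.2), the feedback inhibitor Socs3 (−1.99 ± 0.39, adjusted p = 0.018), lost without WT-labelled untreated library 3 or either KO-labelled untreated library (up to 0.081).

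No Schlafen gene passed between untreated lines in limma (2 of 8 adjusted over the list alone; 1 higher and 1 lower with the block; list adjusted p = 1). Slfn10-ps, with 1 read in KO-labelled cells, was lower by a ratio of 9.0 (95% counting interval 1.35 to 382, adjusted p = 0.051) and passed with the block (0.016). Slfn8, with 3 reads in WT-labelled cells, had a ratio of 2.41 (0.469 to 15.5). Slfn5 and Slfn9 had 1.31 ± 0.93 and −0.25 ± 0.83 (adjusted p = 0.49 and 0.91), and Slfn1, Slfn3 and Slfn4 were at or under the floor in both.

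Genes of cell identity and imprinting also differed between the untreated lines. Dlk1, an imprinted Notch ligand relative, was 1440 ± 361 in WT-labelled and 18.4 ± 0.686 in KO-labelled cells (−6.18 ± 0.32, adjusted p = 1.7e-05), and 3 of 9 imprinted genes were lower (7 of either sign adjusted over the list alone, 4 higher and 3 lower with the block). The others were Igf2 (−7.40 ± 1.28, lost without KO-labelled untreated library 2, adjusted p = 0.082) and Ndn (−1.94 ± 0.33, lost without KO-labelled untreated library 1, 0.061). That list had a median of 0.35 but a mean of −1.1 and adjusted p = 0.7. Of 34 fibroblast and matrix genes 1 was higher and 2 lower (3 adjusted over the list alone; 6 and 6 with the block; list adjusted p = 0.7), led by the proteoglycan Dcn (−4.44 ± 0.18, adjusted p = 7e-06). Lum, a related proteoglycan, was lower (2 reads in KO-labelled cells, ratio 36.3, 95% counting interval 9.81 to 304; lost without KO-labelled untreated library 2, 0.058). Col6a3, a collagen chain, was higher (2.37 ± 0.52; lost without WT-labelled untreated library 2 or 3, WT-labelled IFN-β library 2 or either KO-labelled untreated library, up to 0.16). Of 20 Hox and positional genes 2 were higher (5 adjusted over the list alone; 8 higher and 2 lower with the block), Hoxa3 (1.47 ± 0.21, adjusted p = 0.0039) and Tbx15 (0.86 ± 0.16, 0.015, lost without WT-labelled untreated library 3 or either KO-labelled untreated library, up to 0.12), with list adjusted p = 0.0014, and adjusted p = 0.7 with an estimated correlation.

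Of 9 muscle and skeletal markers 2 were higher in untreated KO-labelled cells (2 adjusted over the list alone; 3 higher and 1 lower with the block; list adjusted p = 0.1). These were the fat-cell regulator Pparg (2.25 ± 0.28, adjusted p = 0.0023) and Acan, a cartilage proteoglycan at least 4.11-fold higher from 0 reads (lost without KO-labelled untreated library 2, 0.079). The list had adjusted p = 0.05 without WT-labelled IFN-β library 1. Of 7 neural markers 2 were higher and 1 lower (4 adjusted over the list alone; 2 higher and 2 lower with the block; list adjusted p = 0.56), Sox2, Mtap2 (2.89 ± 0.48) and Nes (−2.09 ± 0.38), the last pair lost without KO-labelled untreated library 2 (0.075 and 0.1). Flt1, an endothelial VEGF receptor, was lower (−2.41 ± 0.39, adjusted p = 0.0072), but 3 of 12 endothelial, 3 of 16 macrophage and 1 of 14 epithelial markers had enough reads to test. Of these, chosen after their values were seen, the macrophage marker Cd14 held 205 to 346 normalised reads in WT-labelled and 58.3 to 147 in KO-labelled libraries (−1.45 ± 0.42 untreated, adjusted p = 0.081, and 0.017 with the block). Csf1r and Cd68 held 15.8 to 58.4 and 26.8 to 46.3 over all libraries, and the epithelial Krt7 0 to 43.6.

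The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 6 WT-labelled libraries and nearly absent from the KO-labelled ones. Untreated Ddx3y was 327 ± 115 against 1 read in KO-labelled cells (ratio 648, 95% counting interval 116 to 25600), Eif2s3y likewise against 1 read (495, 88.5 to 19600), and Kdm5d and Uty, at 0 reads, were at least 35.8-fold and 33.3-fold lower. Xist, the RNA of the inactive X chromosome, held 8 reads over all 10 libraries.

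Few genes of the stress, growth and metabolic lists passed between the untreated lines. The heat-shock gene Dnajb1, which lies among higher neighbours on chromosome 8, was higher (1.25 ± 0.13, adjusted p = 0.00079), the only passing gene of 17 in the stress list (1 adjusted over the list alone; 4 higher and 1 lower with the block). The stress list had adjusted p = 0.035, 0.3 with the block, and adjusted p = 0.74 with an estimated correlation, and did not pass without WT-labelled untreated library 2 (0.058) or 3 (0.27) or KO-labelled untreated library 1 (0.32). Of 18 cholesterol synthesis genes 1 was lower (1 adjusted over the list alone, 8 with the block), Dhcr7 (−1.05 ± 0.22), lost without WT-labelled untreated library 2 or 3 or either KO-labelled untreated library (up to 0.11). The cholesterol list was lower by a median of −0.74, with adjusted p = 0.0054 (2e-04 with the block), and adjusted p = 0.74 with an estimated correlation, and did not pass without WT-labelled untreated library 2 (0.081) or 3 (0.07) or KO-labelled untreated library 1 (0.32). Of 22 p53 genes 2 were higher and 1 lower (6 adjusted over the list alone; 6 and 3 with the block; list adjusted p = 0.32), which were Perp, Eda2r, a TNF receptor relative (1.61 ± 0.34, lost without either KO-labelled untreated library, up to 0.16), and the death receptor Fas (−4.34 ± 0.73, adjusted p = 0.0087, and 0.059 without KO-labelled untreated library 1). Of 31 cell cycle genes 1 was lower (1 adjusted over the list alone; 2 higher and 5 lower with the block; list adjusted p = 0.52, and 0.017 without KO-labelled untreated library 1), the cyclin Ccne1 (−0.85 ± 0.19; lost without WT-labelled untreated library 1 or 2, any WT-labelled IFN-β library or KO-labelled untreated library 2, up to 0.21). None of 14 contractile genes passed in limma (0 adjusted over the list alone, 0 with the block) nor of 15 immediate early genes (0 adjusted over the list alone; 2 higher and 4 lower with the block), with list adjusted p = 1 for both.

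With IFN-β present, most of these differences between the lines were there too. Genes higher in KO-labelled cells included Perp (7.58 ± 0.58), the intracellular peptidoglycan sensor Nod2 (5.93 ± 0.87), from 13.0 ± 12.7 in WT-labelled (SD, n = 3) to 597 ± 27.6 in KO-labelled cells (n = 2), Klhl13 (6.42 ± 0.69), and Lyl1, Meox1 and Slc6a15 with 2, 2 and 1 reads in WT-labelled cells (ratios 430, 118 to 3560; 160, 43.9 to 1330; and 470, 83.7 to 18600). Sox2 was at least 37.3-fold higher from 0 reads, and Pcdh10 held 3 reads in WT-labelled cells (ratio 136, 46 to 663). Lower were Saa3 (−9.65 ± 0.99), Cxcl5 (−9.20 ± 0.53) and Serpina3g (2 reads in KO-labelled cells, ratio 440, 122 to 3640), and Pcdh7, Hp and Shroom2, at 0 reads, were at least 138-fold, 91.0-fold and 75.4-fold lower. In all 359 genes were higher and 448 lower (1566 and 1637 with the block). The block total of 3203 was 2031 and 2027 without WT-labelled IFN-β library 1 and 2, and 1489 and 1211 without KO-labelled IFN-β library 1 and 2. The total of 807 was 520, 408 and 398 without WT-labelled IFN-β library 1, 2 and 3, and 329 and 285 without KO-labelled IFN-β library 1 and 2. In both treatments 298 genes were higher (10.8 if independent) and 324 lower (14.5), and the log2 differences correlated across genes at Pearson's r = 0.94.

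NF-κB target genes were again lower with IFN-β, 15 of 49 (23 adjusted over the list alone, 32 with the block), with a median of −1.4 (adjusted p = 4e-14, and adjusted p = 0.013 with an estimated correlation). C3 was 3600 ± 2150 in WT-labelled and 23.8 ± 6.63 in KO-labelled cells (−7.00 ± 0.58, adjusted p = 0.00024), and Mmp3, at 0 reads, was at least 78.2-fold lower. Il6, by contrast with its untreated difference, had −1.19 ± 0.59 (adjusted p = 0.295, and 0.0308 with the block). Nfkbia had −0.97 ± 0.30 (adjusted p = 0.1, and 0.006 with the block).

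Few interferon-stimulated genes passed between the treated lines. Of 60, 1 was lower (1 adjusted over the list alone; 5 higher and 5 lower with the block), Rsad2 (−2.71 ± 0.47, adjusted p = 0.0099, lost without either KO-labelled IFN-β library, up to 0.077), which lies among lower neighbours on chromosome 12, and the list's median was 0.079 (adjusted p = 0.73), or 0.28 (0.049) without all libraries numbered 1. Ifit1 (−0.52 ± 0.67, adjusted p = 0.74) and Isg15 (0.39 ± 0.48, 0.72) did not pass. Cxcl10 was 49100 ± 11000 in WT-labelled and 21100 ± 10100 in KO-labelled cells (−1.29 ± 0.41, adjusted p = 0.11, and 0.03 with the block). Of the 8 Schlafen genes 3 were lower (4 adjusted over the list alone): Slfn2, Slfn1 (2 reads in KO-labelled cells, ratio 15.3, 95% counting interval 3.99 to 130, adjusted p = 0.042) and Slfn3 (3 reads, 8.60, 2.73 to 43.6, adjusted p = 0.034). Slfn1 lost its call without any 1 of the 10 libraries (up to 0.22), Slfn3 without any but WT-labelled untreated library 2 and the KO-labelled untreated libraries (up to 0.17). Slfn4 (−2.69 ± 0.76, adjusted p = 0.074) passed with the block (0.018), and Slfn5, Slfn8, Slfn9 and Slfn10-ps had −0.18 ± 0.93, −0.12 ± 0.58, 0.33 ± 0.83 and −0.70 ± 0.49 (adjusted p from 0.48 to 0.95). The Schlafen list had a median of −1.4 and adjusted p = 0.013, 0.16 with the block and 0.099 without KO-labelled IFN-β library 1, and adjusted p = 0.73 with an estimated correlation. Of 17 GTPases 1 was lower (2 adjusted over the list alone, 5 with the block), Gbp4, at 349 ± 358 against 6.21 ± 2.81 (−5.03 ± 0.89, adjusted p = 0.011, lost without either KO-labelled IFN-β library, up to 0.082), which lies among lower neighbours on chromosome 5. The GTPase list had adjusted p = 0.022, and adjusted p = 0.73 with an estimated correlation, and did not pass with the block (0.16) or without WT-labelled IFN-β library 2 (0.059) or 3 (0.062) or KO-labelled IFN-β library 1 (0.38).

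Neighbouring genes on several chromosomes differed together between the lines, and these genes were chosen after their values were seen. Expressed genes here are those with an average log2 CPM of at least 1, and higher or lower is the mean over both treatments. On chromosome 8, from 84125989 to 88751945 (GRCm38), all 50 expressed genes from Podnl1 to Cyld were higher in KO-labelled cells, with a median log2 difference of 1.38 untreated and 1.42 with IFN-β, and 38 of them passed untreated. Lyl1, Nod2 and Cyld lie in this stretch, as does the adenylyl cyclase Adcy7 (3.16 ± 0.42, adjusted p = 0.0028). Nearby, from 82763607 to 83664694, 8 of 9 expressed genes were higher (median 1.25 and 1.29) and 7 passed untreated, Dnajb1 among them. On chromosome 9, from 7184520 to 8042823, all 8 expressed genes were lower and 6 passed untreated. Yap1, the transcriptional coactivator of the Hippo pathway, was 46200 ± 7690 in WT-labelled and 2840 ± 157 in KO-labelled cells (−4.01 ± 0.20, adjusted p = 1.5e-05), and the NF-κB targets Birc3 (−5.15 ± 0.44), Birc2 (−2.42 ± 0.32), Mmp3 and Mmp13 lie in the same stretch. On chromosome 19, from 34290666 to 34640743, all 8 expressed genes were lower (median −2.84 untreated and −0.78 with IFN-β) and 7 passed untreated. Fas and the interferon-stimulated Ifit2, Ifit3, Gm14446 and I830012O16Rik lie there, with Ifit1 next to it. Stretches of 5 or 6 expressed genes are no longer than the longest in 100 permutations of gene positions (6). On chromosome 5, from 90603076 to 91093646, all 6 expressed genes were lower (median −2.78 untreated and −2.50 with IFN-β) and 4 passed untreated (Cxcl5, Ppbp, Cxcl3 and Mthfd2l). The NF-κB targets Cxcl5, Cxcl1 and Cxcl2 lie within it, the last pair under that expression level. From 104525735 to 105490074 on the same chromosome, 5 of 6, Gbp4 among them, were lower (median −1.51 and −2.52) and 0 passed untreated. On chromosome 12, from 25093799 to 27342574, all 5 were lower (median −3.36 and −2.71) and 4 passed untreated (Rnf144a, Rsad2, Cmpk2 and Sox11). All 6 were higher on chromosome 3 from 107741048 to 108086651 (median 1.16 and 1.38), with the NF-κB target Csf1 inside, and on chromosome 8 from 57511907 to 61131346 (1.12 and 0.97), with 2 (4933431E20Rik and Gstm5) and 1 (2700029M09Rik) passing untreated. On chromosome 17, from 12966796 to 14404790, all 5 were lower (−1.06 and −1.40), and 1 passed, the NF-κB target Sod2. All 5 were also lower on chromosome 5 from 5579278 to 8069379 (−1.40 and −1.31; A330021E22Rik, Steap1 and Steap4 passed). They were higher on chromosome 3 from 92483952 to 93526287 (2.19 and 1.60; Sprr1a passed) and on chromosome 8 from 70835129 to 70897412 (1.53 and 1.39; Kcnn1, Ccdc124 and Slc5a5 passed). The expressed genes of chromosome 3 were shifted up as a whole, with a median of 0.43 and 85.5% of 545 genes higher. Those of the X chromosome were shifted down (−0.33, 19.9% of 361 higher), as were those of chromosome 12 (−0.32, 16.1% of 372). Chromosomes 7 (−0.24, 25.4% of 791) and 1 (−0.2, 25.7% of 615) lay lower too, and chromosome 6 higher (0.27, 77.5% of 521). Medians of the rest, Y aside, ran from −0.16 (chromosome 18) to 0.18 (chromosome 10).

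**Figure D4:**
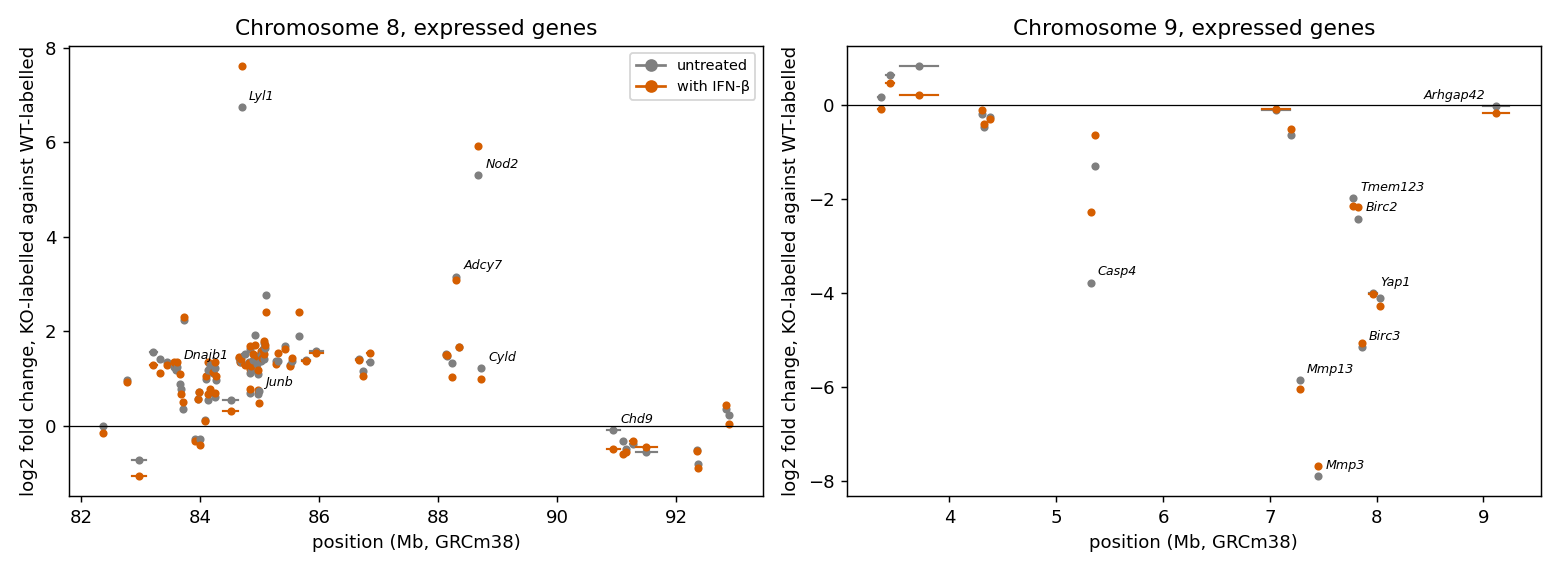
Log2 fold change of KO-labelled against WT-labelled cells, untreated (grey) and with IFN-β (orange), for expressed genes by position (Mb, GRCm38) on part of chromosome 8 and of chromosome 9, each bar spanning a gene with a dot at its middle. The 50 genes from Podnl1 to Cyld all lie above 0 untreated, with a median of 1.38, and Mmp13, Mmp3, Birc2, Birc3 and Yap1 lie below −2.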

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

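The tests of interferon-stimulated gene levels with IFN-β were chosen only after the result was seen, while those of a differing baseline among single genes were planned.

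Each result here is a difference between the KO-labelled and WT-labelled cells in their response to IFN-β, found by testing the interaction. As lists, the interferon-stimulated genes responded more in KO-labelled cells by a median log2 difference of 0.36, the interferon-inducible GTPases by 0.68 and the MHC class I genes by 0.22. The Schlafen genes responded less, at −1.5, in a list that includes Slfn2 and was not tested without it. None of the 4 lists passed with an estimated correlation (adjusted p = 0.22, 0.61, 0.76 and 0.12). Slfn2 itself had −3.31 ± 0.57 in DESeq2 (adjusted p = 0.00014), while limma and edgeR called 0 genes (36 and 39 at an unadjusted p under 0.05). Both counts are below the share of 0.05 expected if no response differed, so these tests were conservative.

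For the larger response of the interferon-stimulated genes, a candidate explanation is a lower untreated level in KO-labelled cells with a like level after IFN-β. The list's median KO-labelled against WT-labelled difference was −0.31 untreated and 0.079 with IFN-β, but the untreated value ran from −0.87 to 0.17 as single libraries were left out, highest without KO-labelled untreated library 1. Without the neighbouring chromosome 19 Ifit genes the untreated list did not pass (−0.20, adjusted p = 0.1), and without all libraries numbered 1 the value with IFN-β was 0.28 (0.049). The planned test of a differing baseline needed genes that passed for the interaction and had 0 in limma, so it decides nothing. An uneven untreated KO-labelled library therefore stays open beside an effect of the genotype or line. With 2 libraries in that group, no value here decides which of them is uneven.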

How the results depend on the processing

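Some tests were chosen after seeing the data. These were all libraries numbered 1 left out, the block over numbers 1 and 2 only, edgeR with TMM and the block, other pseudocounts, and lists without neighbouring genes. Of 4734 alternatives for 207 named-gene results, 4352 kept direction and side of the threshold, 346 fell below it, 36 rose above it and 0 reversed. Of 1345 for 95 list results, 1192 kept both, 79 fell below, 61 rose above and 13 reversed, and of 119 for counts 94 stayed within 1.5 times. Where counts moved, the cause was not tested unless stated. The block gave 609 genes for IFN-β in WT-labelled cells, 429 in KO-labelled, 3275 and 3203 for KO-labelled against WT-labelled untreated and with IFN-β, and 386 that rose in both genotypes, since it removes spread the replicate numbers share. With edgeR and the block these were 619, 425, 3343 and 3285, and over numbers 1 and 2 only 356, 2318 and 2198 (KO-labelled, untreated, with IFN-β). DESeq2 gave 1490 and 1483 between genotypes and 1 for the interaction. Fitting only the groups compared, which leaves fewer samples to estimate spread, gave 3 in KO-labelled cells and 246 untreated. For lists, the block brought the NF-κB targets past the threshold in WT-labelled cells (median 0.054, adjusted p = 0.039) and the interaction (0.062, 0.047), neither with an estimated correlation (0.12 and 0.29), and lost immediate early genes in WT-labelled cells (0.057), stress genes untreated (0.3), and Schlafen genes and GTPases with IFN-β (0.16 each). Of the 207 named-gene results, 8 rose past the threshold with it and 0 fell below. The fry test asks whether a list changes at all, while camera compares it with other genes, so their calls answer different questions. The estimated correlation gained 0 list calls, and fry gained 10, such as p53 targets (0.00063) and imprinted genes (0.0051) untreated. They lost 21 and 15, among them NF-κB targets in KO-labelled cells (0.1, adjusted p = 0.15 and 0.13), interferon-stimulated genes untreated (−0.31, 0.74 and 0.28) and their interaction (0.36, 0.22 and 0.98). Without all libraries numbered 1, interferon-stimulated genes untreated reversed to 0.11 (0.87) and contractile genes to −0.52 (0.037), interferon-stimulated genes with IFN-β passed at 0.28 (0.049), and the NF-κB interaction at 0.18 (0.0034). Without the chromosome 5 and 9 neighbours, the NF-κB targets passed in WT-labelled cells (0.063, 0.039), and without the chromosome 19 ones the interferon-stimulated genes did not untreated (−0.2, 0.1).

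Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 194 to 291 genes in WT-labelled cells, 132 to 217 in KO-labelled, 340 to 685 untreated, 285 to 850 with IFN-β, 128 to 191 that rose in both genotypes, and 0 to 0 for the interaction. List medians ran from 4.6 to 4.9 (WT-labelled), 4.3 to 6 (KO-labelled), −0.87 to 0.17 (untreated), −0.12 to 0.31 (with IFN-β) and −0.089 to 1.1 (interaction) for interferon-stimulated genes. For NF-κB targets they ran from 0.021 to 0.32, 0 to 0.41, −1.9 to −0.93, −1.9 to −0.97 and −0.03 to 0.19. Interaction medians ran from −0.041 to 0.95 for GTPases, −0.22 to 0.73 for MHC class I, −0.24 to 0.18 for cell cycle, −1.6 to 1.7 for contractile (−0.73 to 1.3 untreated), −0.45 to 0.4 for cholesterol and −0.22 to 0.16 for stress genes. Depth limits genes near the floor of 3 reads per library.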

Other observations

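The tests of copy number, chromosome shifts, stretches, the NF-κB targets and the Y-linked genes were chosen only after the results were seen, while those of Hox genes, the cell cycle list and the splits were planned. The NF-κB target genes were lower in KO-labelled cells with and without IFN-β. A candidate explanation is the Slfn2 genotype itself, which the design names and which was not tested apart from the line. Without Birc2, Birc3, Mmp3 and Mmp13, which lie in the chromosome 9 stretch, the untreated list still passed (adjusted p = 8.9e-13). It also passed without these and Cxcl1, Cxcl2 and Cxcl5 of a chromosome 5 stretch (4.4e-11), and without the libraries numbered 1 (5.7e-18). This argues against the values of the left-out genes themselves, and against those libraries, as the whole cause. Whether a stretch, such as those that hold Birc2, Birc3 or Cyld, lowers NF-κB target genes elsewhere was not tested and stays open. Differences between the lines other than the Slfn2 genotype stay open, as 4 Y-linked genes that only the WT-labelled line expressed passed the test between them, so the lines differ beside the genotype. With 1 line of each genotype, line and genotype cannot be told apart for these genes.

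Genes of whole chromosomes shifted together between the lines. The SD of the chromosome medians was larger than in every permutation of gene positions (p = 0.001, the smallest that 1000 permutations can give), and so was the longest stretch, 50 genes on chromosome 8 (p = 0.01, the smallest that 100 can give), which argues against chance scatter. Copy number differences may account for such shifts. Of the 767 genes that differed between untreated lines, 644 had a position and an average log2 CPM of at least 1. A share of 0.17 of these kept under 0.5 of their log2 fold change once the median of 20 neighbours was subtracted (14.5% to 20.5%, exact binomial). A shift shared within segments of more than 20 expressed genes thus does not account for most of them. An effect of a segment on genes elsewhere was not tested. With 4 neighbours, for segments of 5 to 20 genes, the share was 0.23 (19.5% to 26.1%). That is below the 0.5 predicted if shifts shared within such segments were the cause. The interval did not lie wholly under the limit set for arguing against such shifts, so they stay open. Changes of fewer genes, and the genes that passed only with the block, were not tested. No DNA measurement was analysed here.

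For the other genes that differed between untreated lines, a different tissue origin or lineage of the lines was tested on Hox and positional genes, 2 of 20 of which passed (10% against 6.23% of all tested genes, one-sided Fisher exact p = 0.36, and 0.021 with the replicate block), which leaves it open. For a growth state or cell cycle difference, the cell cycle list had a median absolute log2 fold change of 0.22, whose bootstrap interval of 0.17 to 0.27 crosses the limit of 0.25, which leaves it open.

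For IFN-β in WT-labelled cells, the real split of the 6 libraries gave 272 genes and the highest other split 0, as 1 of 10 splits reached that count. With the block, among 4 splits that part as many pairs, 1 reached the real count of 609 and the highest other was 0. The splits are too few for a share under 0.05. Another split, which parts fewer pairs (1), gave 1180 genes with the block, which points to a structure of the samples whose cause was not tested. The other splits that part 1 pair gave 0 with the block.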
